A study of Homo sapiens with 9 samples.

How the data were processed

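The samples came from LNCaP clone 7-11, in which RSL1 induces a recombinant processed AIbZIP. Per the labels, cells of passage 42 were plated in 24 dishes of 10 cm and given 500 nM RSL1 for 6 h or 24 h, or DMSO as vehicle, in medium with serum. Per the labels, dishes were pooled 2 by 2 into 4 samples per group, of which 3 were hybridised to Affymetrix U133 Plus 2.0 arrays from 20 ug of total RNA and the other was kept for immunoblotting. The labels differ on the controls, which a field places before RSL1 was added and the treatment text calls vehicle treated, and their harvest time is not given. The replicates therefore come from pooled dishes of a single plating and show its spread only. No cells without the transgene were given RSL1 in this set, so an effect of the compound cannot be separated from one of AIbZIP. The labels name 2 array lots without assigning them to samples.

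The authors deposited linear intensity values per probe set made with RMA, per the submitters' processing notes, which give no version. These deposited intensities were taken to log2, and no further normalization was made for the main analysis. All 9 arrays and all columns of values were used. Of 54675 probe sets, 62 were array controls, 41091 carried exactly 1 gene symbol, 1801 carried several and 11721 carried none. Gene names came from the platform table, and 41037 of the single-symbol probe sets had their gene ID in the reference table of names (assembly GRCh38.p14, used for names only), which changed no symbol. Each gene was represented by its probe set of highest mean over all arrays, which left 19775 genes. Probe sets without a single symbol were tested apart.

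Genes were compared with limma 3.58.1 in R 4.3.3, with the 3 groups in the same linear model and empirical Bayes moderation. The contrasts were 6 h against control, 24 h against control and 24 h against 6 h, with an F test over the groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum, and "rose" and "fell" are used of called genes. Fold changes, their SEs on the log2 scale and group means with SDs are given from the same values. Complete separation of 3 arrays from 3 others is expected by chance in 10% of genes, and the smallest two-sided exact p for such groups is 0.1, so single-gene calls rest on the spread pooled over genes. The number of arrays limits precision. Signal was not tested against background, so folds of genes with a group mean below the array medians are uncertain in size.

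Gene lists, 22 in number, were written from general knowledge before the data were examined, as were the comparisons, the main tests and the first set of alternatives. They cover the CREB3 family, ER, transport and Golgi functions, stress responses, lipid, androgen and hypoxia genes, cell cycle, p53, signalling targets and cell type markers. Members without a probe set of their own were not analysed here. Lists were tested with camera in limma at a preset correlation of 0.01, adjusted over all lists and contrasts. The same test with an estimated correlation gave no call (0, 0 and 0 lists for the 3 contrasts, against 3, 3 and 4 at an unadjusted p under 0.05), and fry in limma gave 4, 16 and 13, where camera gave 7, 10 and 11. The fry calls are those of its directional test, which can miss lists whose members move both ways. For each list the calls adjusted over the list alone are given beside those over all genes.

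The genes named in the report were set by rule: the induced gene, the 10 largest called rises and falls at each time and the 5 largest in each direction between the times, among genes with a group mean above the median of gene means and all arrays of both groups apart, and for each list the called members of smallest adjusted p, or the member of smallest p where none passed. The rule allowed up to 4 members of a list. Limiting it to 2 members, naming 5 genes of opposite direction, examining 10 gene families with 2 members named in 5 of them, Fisher's exact test of the transport and chaperone calls, and dividing the controls were decided after values were seen.

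Whether the replicate numbers pair the arrays was checked before fits with and without pairs were compared, by correlating deviations from group means, with a pair counted when r exceeded 0.1. Arrays of the same number correlated at 0.528, 0.216 and 0.217 between control and 6 h and at 0.501, 0.231 and 0.534 between 6 h and 24 h, which met the rule. Between control and 24 h they correlated at 0.52, 0.0827 and 0.228, which did not. Among the controls, the third arrays at 6 h and 24 h correlated more with control 2 (0.377 and 0.398) than with control 3. The labels do not state pairs, so the unpaired fit was kept and the fit with the replicate number as a block is given where it changes a call or a count by more than 1.5-fold, and for 24 h against control only in the closing section.

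Array quality was checked on the control probe sets. The 3' minus 5' difference of GAPDH was 0.018, 0.011 and 0.033 (log2, control, 6 h and 24 h) and that of ACTB 0.171, 0.19 and 0.147. Exact permutation tests between groups gave p from 0.3 to 0.9 for these and the spike controls, with 0.1 the smallest possible. The 24 h replicate 2 array had the lowest poly-A spikes, 4.89 against 5.61 to 6.09 in the others, and the lowest hybridisation spikes, 10.40 against 10.79 to 11.20.

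Code was tested on simulated data in which 200 of 19775 genes were changed, 50 at each size. Every simulated array had each gene's moderated spread from the fit of all 3 groups. In the 6 h comparison, 18%, 84%, 100% and 100% of genes changed 1.25-, 1.5-, 2- and 4-fold were recovered, and 10 unchanged genes were called. In the 24 h comparison the shares were 14%, 76%, 100% and 100%, and 7 unchanged genes were called. Both comparisons had the same simulated spread, so these shares do not rank them in power. A simulated shifted list was called and unshifted lists were not.

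Alternatives tried were leaving out genes below the median of gene means (6.339 log2), quantile normalization again, median centring, the mean of all probe sets of a gene, all probe sets, an intensity trend with a robust prior, a change of at least 1.5-fold, an adjusted p under 0.01, the replicate block, only the groups compared in the fit, camera with an estimated correlation, fry, and leaving out each array, where list counts of 1 to 3 genes often changed by 1. Cyclic loess normalization, quantile normalization without the 24 h replicate 2 array, and quantile normalization with the replicate block were added after values were seen. Calculations outside R used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures matplotlib 3.10.9. The immunoblot samples were not used here.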

Results

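Transcript levels were measured on Affymetrix U133 Plus 2.0 arrays in clone 7-11, an LNCaP line in which the compound RSL1 switches on a recombinant, processed form of AIbZIP. LNCaP is an established, androgen-responsive prostate cancer line. AIbZIP, encoded by CREB3L4, is a transcription factor of the CREB3 family that is made as a protein of the endoplasmic reticulum (ER) membrane, and the processed form is the part released from it. Cells received 500 nM RSL1 for 6 h or 24 h or served as controls, with 3 arrays in each of the 3 groups. The treatment text of the labels calls the controls vehicle treated, while another field places them before RSL1 was added. Array medians lay between 40.1 and 42.1 linear intensity units, and 19775 genes were tested. The first principal component held 59.5% of the variance and placed the 24 h arrays apart from the other arrays. All changes below are log2 differences or fold changes of RMA values, and every adjusted p of a gene comes from limma. For each list member or leading gene named below as risen or fallen, all 3 RSL1 arrays lay on the same side of all 3 control arrays. Chance gives this to 10% of genes. It was a condition for naming a leading gene, and list members were taken by smallest adjusted p, so it adds no support to their calls.

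The induced gene was examined first. The probe set of CREB3L4 read 8.80 ± 0.19 in the controls, 8.69 ± 0.18 at 6 h and 8.54 ± 0.11 at 24 h (log2, mean ± SD, n = 3 arrays each). Neither difference from the controls passed in the fit without pairs, with log2 changes of -0.10 (adjusted p = 0.95) at 6 h and -0.26 (adjusted p = 0.165) at 24 h. Whether this probe set can detect the recombinant transcript is not given in the sources used here, so its level does not check the labels. In contrast, CREB3, a related factor of the same family, rose 2.30-fold at 6 h and 4.07-fold at 24 h (SE of each log2 change 0.121; adjusted p = 0.000166 and 5.56e-07). CREB3 was the 1 member of the 8-member CREB3 family list to pass at either time, also when adjusted over the list alone. That list was not called by camera at 6 h (adjusted p = 0.993, median -0.08, mean 0.08) or at 24 h (adjusted p = 0.493). The directional test of fry asks whether members shift in the same direction, without setting them against other genes. It called the list at 24 h (adjusted p = 0.0053, median 0.02, mean 0.23).

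The first comparison asked which transcripts had changed 6 h after RSL1 was added. HES1, a transcriptional repressor and Notch target, rose 5.54-fold, from 6.25 ± 0.39 to 8.72 ± 0.11 (log2, mean ± SD, n = 3 arrays each). Nearly as large were the rises of MTUS2, which encodes a microtubule-associated protein (5.22-fold), IKBIP (4.89-fold), SIAH2, a ubiquitin ligase (4.88-fold), and THBS1, the matrix glycoprotein thrombospondin (4.66-fold). KCNK1, a potassium channel, rose 3.90-fold, CCDC110 3.81-fold, GFPT1, the rate-limiting enzyme of the hexosamine pathway, 3.77-fold, KLF4 3.68-fold and ID2 3.53-fold. The SEs of these 10 log2 changes lay between 0.113 and 0.226, and the adjusted p values between 3.91e-06 and 0.000538. The controls of MTUS2 (4.72) and CCDC110 (4.96) read below the array medians (5.33 to 5.37 in log2), so the size of their folds is uncertain.

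Falls at 6 h were smaller. The developmental transcription factor SOX4 was 2.63-fold lower (9.68 ± 0.07 against 11.07 ± 0.04, log2, mean ± SD, n = 3 arrays each; adjusted p = 1.74e-05). Lower too were BTG1, an antiproliferative factor (2.17-fold lower), LRRN1 and the growth regulator MYC (each 2.08-fold lower), ID1 (2.07-fold lower) and PTCH1, the Hedgehog receptor (2.03-fold lower). The Wnt receptor FZD5 was 1.91-fold lower, KLF10 1.90-fold, HOXC6 1.83-fold and EPPK1, a cytolinker, 1.83-fold. The fall of KLF10 (adjusted p = 0.0113) did not pass without control 2, control 3, 6 h replicate 1 or 6 h replicate 3 (adjusted p = 0.0565, 0.0597, 0.0533 and 0.0543). That of EPPK1 (adjusted p = 0.0104) did not pass without control 2 (0.0513) or control 3 (0.0554).

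Part of the genes of the early secretory pathway rose at 6 h, and the calls of their lists below did not hold with an estimated correlation. Of 37 measured transport coat and cargo receptor genes, which move proteins between the ER and the Golgi, 12 rose and the other 25 did not pass (19 rose when adjusted over the list alone). The 12 rises became 4 without control 1, 5 without control 3, and 6, 4 and 4 without 6 h replicates 1, 2 and 3. KDELR3, a receptor that returns ER proteins from the Golgi, rose 2.97-fold, and SEC24D, a cargo adaptor of the COPII coat, 2.92-fold (adjusted p = 0.00014 and 0.000211). The median log2 change of the list was 0.29 (camera adjusted p = 1.66e-16; adjusted p = 0.312 with an estimated correlation). Of 25 genes of Golgi structure and glycosyltransferases, 4 rose (15 rose and 1 fell when adjusted over the list alone; 2 rose without control 1, control 3, 6 h replicate 2 or 6 h replicate 3, and 7 without 24 h replicate 1 or 2), with a median of 0.27 (camera adjusted p = 3.5e-10; adjusted p = 0.191 with an estimated correlation). Among them were the Golgi matrix genes GORASP2 (1.82-fold) and GOLGA5 (1.74-fold). In the list of N-glycosylation in the ER 2 of 24 members rose, also when adjusted over the list alone (median 0.06, camera adjusted p = 0.00524; adjusted p = 0.598 with an estimated correlation). These were GFPT1, which supplies the amino sugar and is not itself an ER glycosylation enzyme, and ALG1, a mannosyltransferase (1.28-fold, adjusted p = 0.0342). ALG1 did not pass without any one of the 6 arrays compared (adjusted p from 0.0674 without control 1 to 0.178 without control 2) or with the intensity trend and robust prior (0.0512).

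The translocation machinery gave a list call with no gene call at 6 h. Of 23 measured genes of ER translocation and signal peptide processing, 0 passed in limma, also when adjusted over the list alone, against 4 higher at an unadjusted p under 0.05. The list was nevertheless shifted upward (median 0.08, camera adjusted p = 0.0143; adjusted p = 0.652 with an estimated correlation). SRPRB, a subunit of the signal recognition particle receptor, was 1.28-fold higher (adjusted p = 0.155), and passed with the replicate number as a block (adjusted p = 0.0458), after quantile normalization again (0.0113) and without 24 h replicate 2 (0.0257). Without control 1 or 6 h replicate 3, the translocation list was no longer called (adjusted p = 0.0789 and 0.109), nor was the N-glycosylation list without 6 h replicate 3 (adjusted p = 0.0668, median 0.03); without control 2 the latter's median was 0.10. Neither list passed in fry (adjusted p = 0.508 and 0.277). ER chaperones and degradation factors did not shift at 6 h (1 of 29 rose, 2 when adjusted over the list alone; median -0.01, mean 0.07; camera adjusted p = 0.197; adjusted p = 0.0248 with the mean of all probe sets). The member that rose was DNAJB9, an ER co-chaperone (1.88-fold, adjusted p = 0.00735).

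Stress and signalling genes moved in both directions at 6 h. In the list of ATF4 targets and amino acid stress, 5 of 22 members fell and 1 rose (8 and 2 when adjusted over the list alone), with a median of -0.19 (camera adjusted p = 3.89e-05; adjusted p = 0.425 with an estimated correlation; fry adjusted p = 0.0519). The 5 falls became 3, 2 and 1 without controls 1, 2 and 3, and 2 and 3 without 6 h replicates 1 and 3, and no member was called without 6 h replicate 2. CEBPB was 1.49-fold lower (adjusted p = 0.00889) and ATF3 1.40-fold lower (adjusted p = 0.0105), both stress-responsive transcription factors. The call of CEBPB was lost without 6 h replicate 2 (adjusted p = 0.0598), and that of ATF3 without control 2 (0.0525), control 3 (0.0598), 6 h replicate 1 (0.0511) or 6 h replicate 2 (0.0651). Of 17 cAMP and CRE targets, 5 rose and 1 fell (5 and 2 when adjusted over the list alone; median 0.04, mean 0.23; camera adjusted p = 0.00937; adjusted p = 0.191 with an estimated correlation). DUSP1, a MAP kinase phosphatase, rose 2.36-fold (adjusted p = 0.000152), while ID1, also a BMP target, fell as given above. This median was 0.02 without control 2 or without 6 h replicate 1, 0.08 without 6 h replicate 2, 0.11 without dim genes and 0.06 with the mean of all probe sets.

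Among 14 cytosolic heat shock genes 3 rose at 6 h (5 when adjusted over the list alone; median 0.05, mean 0.25; camera adjusted p = 0.00191; adjusted p = 0.425 with an estimated correlation). The co-chaperone BAG3 rose 2.98-fold (adjusted p = 1.17e-05) and HSPA6 1.64-fold (adjusted p = 0.00302). All 3 controls of HSPA6 read below the array medians, so the size of its fold is uncertain. The call of this list ended when dim genes were left out (adjusted p = 0.064, median -0.01); its median was 0.00 with the mean of all probe sets, 0.08 without control 2, 0.11 without 6 h replicate 1 and 0.02 without 6 h replicate 3. Immediate early genes did not shift as a list (2 of 19 rose and 4 fell, 3 and 5 when adjusted over the list alone; median -0.01, mean 0.02, direction down; camera adjusted p = 0.766). Only 2 fell without control 2, control 3 or 6 h replicate 3. JUN rose 2.13-fold (adjusted p = 9.22e-05), whereas MYC fell as given above.

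The remaining lists were not called by camera or by the directional test of fry at 6 h. The mixed test of fry, for members moving in either direction, gave unadjusted p = 1.04e-07 for androgen and 9.5e-10 for p53 genes. It gave 2.31e-05 for cholesterol, 0.000174 for hypoxia, 0.00295 for luminal and 0.000383 for stromal genes. For the others it gave 0.11 to 0.951. Of 20 androgen response genes 3 rose and 2 fell (4 and 4 when adjusted over the list alone; 2 and 1 without control 2, control 3, 6 h replicate 1 or 6 h replicate 2; median -0.04, mean 0.00; camera adjusted p = 0.766). FKBP5, an androgen-induced immunophilin, rose 1.82-fold, and PMEPA1 fell with a log2 change of -0.58 (adjusted p = 0.000995 and 0.00131). Of 19 p53 and apoptosis genes 3 rose and 2 fell (3 and 3 when adjusted over the list alone; 1 and 1 without control 1, control 3, 6 h replicate 1 or 6 h replicate 3; camera adjusted p = 0.589), with TP53INP1 2.74-fold higher (adjusted p = 3.9e-05) and SESN1 1.78-fold lower (adjusted p = 0.000169). In the list of cholesterol and fatty acid synthesis 2 of 18 members rose (4 when adjusted over the list alone and 4 without 24 h replicate 1; median -0.01, mean 0.11; camera adjusted p = 0.0825, 0.0359 with the mean of all probe sets, and 0.0178 without control 2, with a median of 0.03). They were STARD4, a sterol carrier (1.88-fold, adjusted p = 0.0012), and FASN, the fatty acid synthase (1.71-fold, adjusted p = 0.00215). Of 18 hypoxia and glycolysis genes 2 rose (2 rose and 1 fell when adjusted over the list alone; median -0.03, mean 0.00, direction up; camera adjusted p = 0.993). ANKRD37 rose 1.75-fold (adjusted p = 0.000473). The rise of HK2, a hexokinase (1.29-fold, adjusted p = 0.0382), did not pass without any one of the 6 arrays compared (adjusted p from 0.0787 without control 2 to 0.156 without 6 h replicate 3) or with the mean of all probe sets (log2 change 0.00, adjusted p = 1).

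No cell cycle gene passed in limma at 6 h. Of 32 measured members 0 passed, also when adjusted over the list alone and at an unadjusted p under 0.05 (median -0.07; camera adjusted p = 0.0758; median -0.03 and adjusted p = 0.419 without 6 h replicate 2, and -0.10 and 0.0111 without 6 h replicate 3; fry adjusted p = 0.44). CDC20, an activator of mitotic protein degradation, had the smallest p, with a log2 change of -0.21 (adjusted p = 0.591). No member passed in limma in the xenobiotic and oxidative stress list (0 of 19; 1 lower at an unadjusted p under 0.05; camera adjusted p = 0.207, fry 0.277) or the interferon response list (0 of 19; 1 higher at an unadjusted p under 0.05; camera adjusted p = 0.186, fry 0.0849, and 0.00908 in camera with the mean of all probe sets), also when adjusted over the list alone. AKR1B10 and IRF7 had their smallest p (log2 changes of -0.18 and 0.21, each with adjusted p = 0.441).

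Cell type markers gave few calls at 6 h. Of 10 luminal epithelial markers 2 rose, also when adjusted over the list alone (median 0.01; camera adjusted p = 0.181), namely the keratin KRT18 (1.57-fold, adjusted p = 0.0116) and the surface protein CD24 (1.61-fold, adjusted p = 0.0131). The call of KRT18 was lost without control 2 (adjusted p = 0.0535), control 3 (0.0639), 6 h replicate 1 (0.0513) or 6 h replicate 2 (0.0545). That of CD24 was lost without control 1 (0.0596), control 3 (0.0778), 6 h replicate 1 (0.0553), 6 h replicate 2 (0.0648) or 6 h replicate 3 (0.0519). Of 14 stromal markers 1 rose, also when adjusted over the list alone (camera adjusted p = 0.394). This was TAGLN, an actin-binding protein (2.07-fold, adjusted p = 0.000798). In limma 0 of 12 neuroendocrine, 0 of 9 basal epithelial and 0 of 10 immune cell markers passed, also when adjusted over the list alone, and 1 of them, a basal marker, was higher at an unadjusted p under 0.05. Camera adjusted p values of the 3 lists were 0.786, 0.269 and 0.925, and fry gave 0.662, 0.432 and 0.945. NCAM1, TRIM29 and TYROBP had the smallest p of each, with log2 changes of -0.13, 0.30 and 0.16 (adjusted p = 0.923, 0.169 and 0.651).

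In all, 385 genes rose and 162 fell at 6 h, of which 256 and 63 changed at least 1.5-fold, and 2000 genes passed at an unadjusted p under 0.05. With the replicate number as a block 605 rose and 412 fell. Rises numbered 242 without control 3, 243 without 6 h replicate 2 and 238 without 6 h replicate 3, and falls 70 without control 2, 75 without control 3, and 81, 63 and 93 without 6 h replicates 1, 2 and 3.

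**Figure D1:**
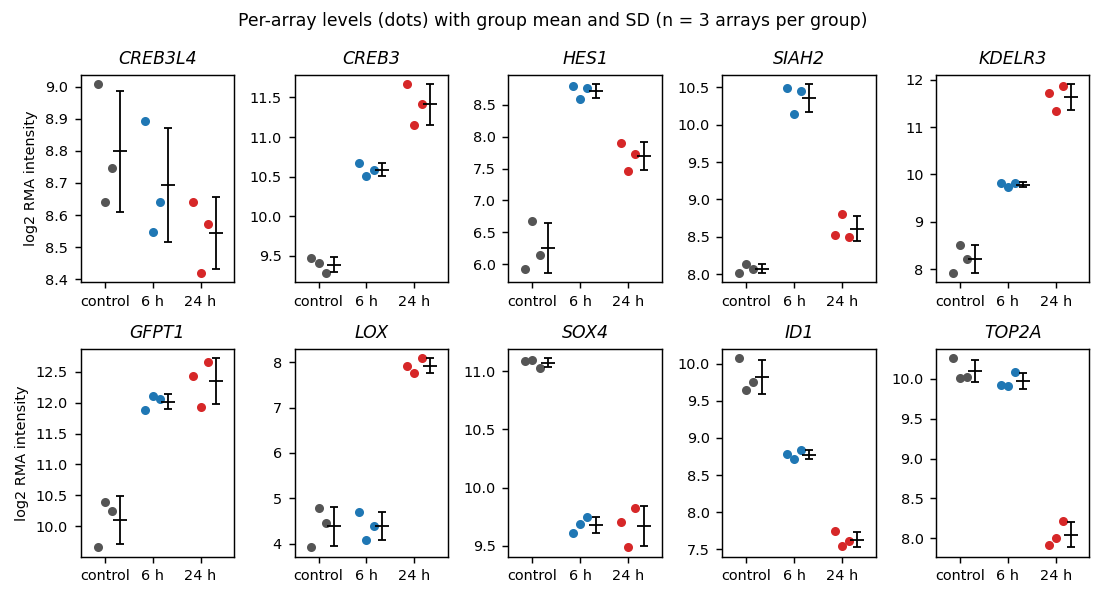
Log2 RMA intensity (vertical axis) of 10 named genes in the 3 groups (horizontal axis): dots are single arrays, and the bar with whiskers is the group mean and SD of 3 arrays. CREB3L4 lay at 8.80, 8.69 and 8.54 in control, 6 h and 24 h arrays, while CREB3 lay at 9.39, 10.59 and 11.41.

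The second comparison asked what had changed by 24 h. TMEM45A, which encodes a membrane protein, rose 18.7-fold, from 5.38 ± 0.96 to 9.60 ± 0.18 (log2, mean ± SD, n = 3 arrays each), MTUS2 14.1-fold and LOX, the collagen cross-linking lysyl oxidase, 11.6-fold. KDELR3 rose 10.7-fold, IKBIP 9.92-fold and AQP3, a water and glycerol channel, 9.45-fold. The next largest rises were those of CUZD1 (8.55-fold), ADA2, a secreted adenosine deaminase (8.15-fold), the noncoding RNA LINC02475 (7.55-fold) and DXO, an RNA decapping enzyme (7.50-fold). The SEs of these 10 log2 changes lay between 0.117 and 0.34, and the adjusted p values between 6.9e-08 and 5.73e-06. In the controls TMEM45A, MTUS2 (4.72), LOX (4.38) and LINC02475 (3.99) lay near or below the array medians (5.33 to 5.37 in log2), LINC02475 below the 25th percentile (4.02 to 4.05). Their signal there was not tested against background, so the size of these 4 folds is uncertain.

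The largest falls at 24 h were mostly of genes used in cell division. ANLN, an actin-binding protein of the cleavage furrow, was 5.60-fold lower (6.77 ± 0.61 against 9.26 ± 0.08, log2, mean ± SD, n = 3 arrays each). KIF23, a midbody kinesin, was 4.95-fold lower, ASPM, a spindle pole protein, 4.86-fold, and RRM2, a subunit of ribonucleotide reductase, 4.53-fold. NDC80 of the kinetochore was 4.31-fold lower, the mitotic kinesin KIF20A 4.24-fold and TOP2A, the DNA topoisomerase, 4.14-fold. Outside this group, DAPK1, a death-associated kinase, was 4.72-fold lower, ID1 4.58-fold and the stress kinase MAP3K20 4.13-fold. The SEs of the 10 log2 changes lay between 0.107 and 0.241, and the adjusted p values between 2.84e-07 and 3.28e-05.

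All 32 cell cycle genes of the list fell at 24 h, also when adjusted over the list alone. The median log2 change was -1.38 (camera adjusted p = 3.93e-33; adjusted p = 0.0682 with an estimated correlation). CCNA2, the cyclin of S phase and mitosis, was 3.45-fold lower, from 8.67 ± 0.04 to 6.88 ± 0.15 (log2, mean ± SD, n = 3 arrays each; adjusted p = 2.85e-07). The list median was -1.27 after quantile normalization again, -1.42 after median centring and -1.16 after cyclic loess. Of 19 p53 and apoptosis genes 7 fell and 4 rose (9 and 5 when adjusted over the list alone; median -0.21), and only 2 rose without control 1 or 24 h replicate 1. Among them SESN1 was 2.36-fold lower and DDB2, a DNA damage sensor, 1.98-fold lower (adjusted p = 1.31e-06 and 9.7e-06). The p53 list was not called by camera (adjusted p = 0.0586, and 0.0474 without 24 h replicate 3) and was called by fry (adjusted p = 0.00694).

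Secretory pathway genes were higher at 24 h. Of 37 transport genes 27 rose and 2 fell, also when adjusted over the list alone, with a median of 0.69 (camera adjusted p = 2.41e-15; adjusted p = 0.312 with an estimated correlation). Besides KDELR3, the cargo receptor MIA3 rose 3.27-fold (adjusted p = 5.56e-07). Of 29 ER chaperones and degradation factors 22 rose (23 when adjusted over the list alone), with a median of 0.55 (camera adjusted p = 4.24e-13; adjusted p = 0.312 with an estimated correlation). EDEM2, which takes part in ER-associated degradation, and CRELD2 each rose 2.10-fold (adjusted p = 6.59e-06 and 8.26e-06). In the Golgi list 13 of 25 members rose and 1 fell (14 and 1 when adjusted over the list alone; 3 fell without 24 h replicate 3; median 0.28, camera adjusted p = 2.27e-05; adjusted p = 0.37 with an estimated correlation). GALNT7, a member of the GALNT family of O-glycan transferases, rose 2.55-fold and the mannosidase MAN1A1 3.06-fold. Of 24 N-glycosylation genes 11 rose and 3 fell (12 and 3 when adjusted over the list alone; median 0.25, camera adjusted p = 0.00298; adjusted p = 0.567 with an estimated correlation), with the smallest adjusted p for GFPT1 (4.73-fold) and ALG1 (1.66-fold). The 11 rises became 7, 6, 7 and 7 without control 2, control 3, 24 h replicate 1 and 24 h replicate 3, and the 3 falls 1, 2 and 2 without control 2, control 3 and 24 h replicate 3. Of 23 translocation genes 7 rose and 2 fell, also when adjusted over the list alone (median 0.20, camera adjusted p = 0.00937; adjusted p = 0.652 with an estimated correlation; fry adjusted p = 0.144). TRAM1 of the translocation channel rose 1.82-fold and SRPRA 1.61-fold. The translocation list was not called without 24 h replicate 3 (adjusted p = 0.13, median 0.11), and its median was 0.12 without 24 h replicate 1. Of its members 12 rose without 24 h replicate 2. The controls of MAN1A1 read below the array medians (log2 4.45), so the size of its fold is uncertain.

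Lipid, androgen and hypoxia genes also shifted upward at 24 h. Of 18 genes of cholesterol and fatty acid synthesis 9 rose (11 when adjusted over the list alone), with a median of 0.27 (camera adjusted p = 1.66e-07; adjusted p = 0.0682 with an estimated correlation). STARD4 rose 3.62-fold and INSIG1, a sterol-regulated ER protein, 2.77-fold (adjusted p = 1.07e-06 and 2.04e-06). Of 20 androgen response genes 11 rose and 2 fell, also when adjusted over the list alone (median 0.31, camera adjusted p = 1.47e-05; adjusted p = 0.25 with an estimated correlation). STEAP4, a metalloreductase read low in the controls (log2 4.70), rose 5.34-fold and NDRG1, which also responds to hypoxia, 4.96-fold (adjusted p = 4.06e-07 and 2.84e-07). Of 18 hypoxia and glycolysis genes 8 rose and 1 fell, also when adjusted over the list alone (median 0.23, camera adjusted p = 0.00524; adjusted p = 0.55 with an estimated correlation; median 0.13 without 24 h replicate 3). ANKRD37 rose 3.16-fold and P4HA1, a collagen prolyl hydroxylase of the ER, 2.60-fold (adjusted p = 4.55e-07 and 6e-06).

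Marker genes were mixed at 24 h. Of 10 luminal epithelial markers 5 rose and 1 fell (6 and 3 when adjusted over the list alone; median 0.42, camera adjusted p = 0.0121; adjusted p = 0.425 with an estimated correlation), and the list was not called without 24 h replicate 3 (adjusted p = 0.0626). CD24 rose 3.81-fold and the keratin KRT8 2.11-fold (adjusted p = 1.27e-06 and 1.01e-05). Of 9 basal epithelial markers 2 rose, also when adjusted over the list alone (camera adjusted p = 0.0516; 0.0455, 0.0429 and 0.0497 without control 3, 24 h replicate 2 and 24 h replicate 3; fry adjusted p = 0.00823). TRIM29 rose 2.94-fold (adjusted p = 7.01e-07). NGFR was 1.36-fold higher (adjusted p = 0.0273), a call lost without control 2 (0.101), control 3 (0.0941) or 24 h replicate 1 (0.0912). Of 14 stromal markers 3 rose and 1 fell (4 and 1 when adjusted over the list alone; camera adjusted p = 0.187, fry adjusted p = 0.0225), with TAGLN 3.92-fold higher and the smooth muscle actin ACTA2 2.04-fold lower (adjusted p = 1.31e-06 and 2.56e-05).

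Among 12 neuroendocrine markers 2 fell at 24 h, also when adjusted over the list alone (median 0.04, mean -0.02, direction up; camera adjusted p = 0.925). The tubulin gene TUBB3 was 1.42-fold lower (adjusted p = 0.0114), a call lost without 24 h replicate 2 (0.054) and after cyclic loess (0.156). DDC, the aromatic amino acid decarboxylase, was 1.36-fold lower (adjusted p = 0.0264). Its call was lost without control 1 (0.0593), control 2 (0.0746), control 3 (0.0765) or 24 h replicate 2 (0.0501), with the mean of all probe sets (0.0735), with only the compared groups in the fit (0.0643) and after cyclic loess (0.176). Of 10 immune cell markers 0 passed in limma, also when adjusted over the list alone, against 2 higher at an unadjusted p under 0.05 (camera adjusted p = 0.408, fry 0.393). TYROBP had the smallest p (log2 change 0.20, adjusted p = 0.126).

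Camera called none of the stress and signalling lists at 24 h, while fry called the cAMP, immediate early and interferon lists (adjusted p = 0.00341, 0.00808 and 0.00233). In the ATF4 list 5 of 22 members rose and 8 fell (7 and 11 when adjusted over the list alone; median -0.20, mean 0.02, direction down; camera adjusted p = 0.919). The falls numbered 5 without any one control or 24 h replicate 2, and without the latter the median was -0.10. VEGFA, the angiogenic growth factor, rose 2.74-fold and ATF3 1.71-fold (adjusted p = 2.42e-05 and 6.19e-05). Of 14 heat shock genes 3 rose and 8 fell (3 and 9 when adjusted over the list alone; median -0.48, camera adjusted p = 0.179), the small chaperone CRYAB rising 2.93-fold and BAG3 2.56-fold (adjusted p = 2.84e-07 and 2.06e-06). Of 17 cAMP and CRE targets 4 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.256). RGS2, a regulator of G protein signalling, rose 4.63-fold (adjusted p = 3.21e-07), and ID1 fell as given above. Of 19 immediate early genes 6 rose and 3 fell (6 and 4 when adjusted over the list alone; camera adjusted p = 0.132), with JUN 2.67-fold and KLF6 2.10-fold higher (adjusted p = 1.69e-06 and 9.51e-06). In the xenobiotic and oxidative stress list 3 of 19 rose and 4 fell, also when adjusted over the list alone (median 0.02, mean -0.03, direction down; camera adjusted p = 0.925). Both subunits of the glutathione-making ligase were among the falls, GCLM (1.52-fold lower, adjusted p = 0.000859) and GCLC (1.88-fold lower, adjusted p = 0.000907). Of 19 interferon response genes 5 rose and 1 fell, also when adjusted over the list alone (3 rose without control 1 or 24 h replicate 2; camera adjusted p = 0.107; 0.0062 without dim genes). The nuclease ISG20 rose 2.47-fold, and IFI6 rose with a log2 change of 0.68 (adjusted p = 3.45e-06 and 0.000178).

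**Figure D2:**
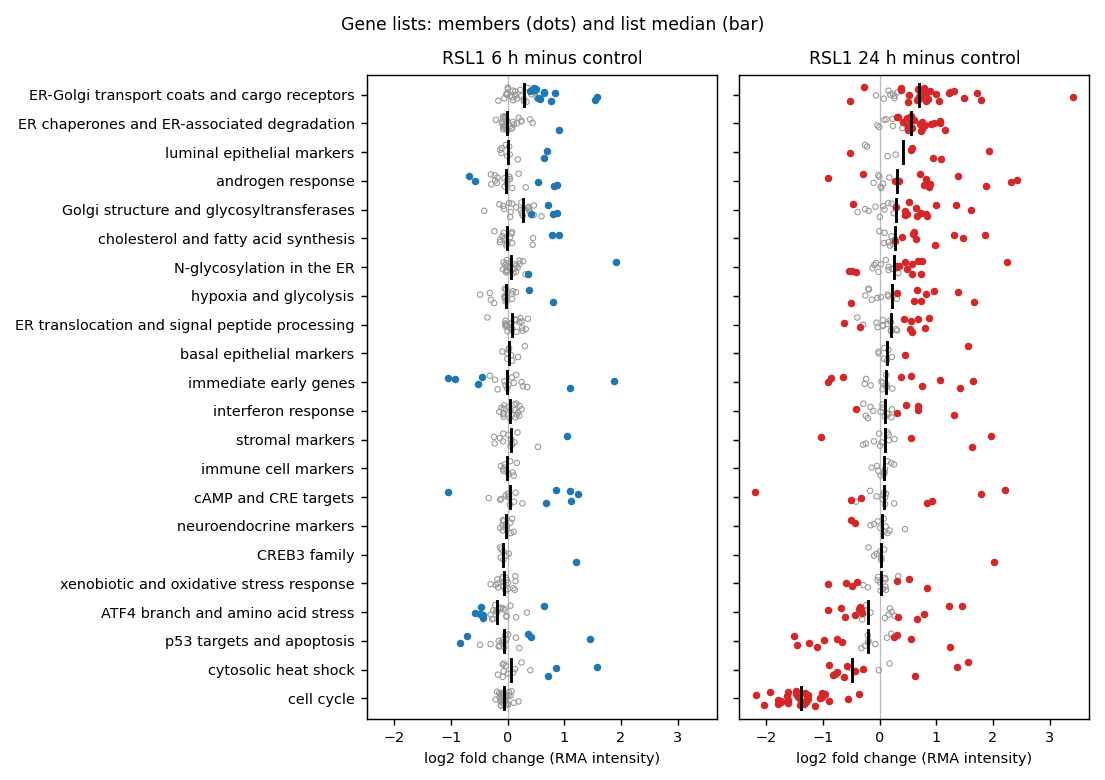
Log2 fold changes of RMA intensity (horizontal axes) at 6 h and at 24 h against control for the members of the 22 gene lists (rows): filled dots passed the gene test, open dots did not, and the black bar is the list median. The cell cycle list has the lowest median at 24 h, -1.38, and the transport list the highest, 0.69.

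In all, 1584 genes rose and 3143 fell at 24 h, of which 755 and 1369 changed at least 1.5-fold, and 6520 genes passed at an unadjusted p under 0.05. The 24 h arrays, replicate 2 above all, read lower for bright genes: among the brightest 10% of genes that array lay at -0.37 (median log2 deviation from the gene mean), against -0.07 to 0.12 in the other arrays. Rises made up 33.5% of the calls, 41.2% after quantile normalization again (1961 rose, 2801 fell) and 47.9% after cyclic loess (2160 rose, 2350 fell), and without 24 h replicate 2 the counts were 1598 and 2665. Under quantile normalization the 24 h medians of the translocation, N-glycosylation, androgen and hypoxia lists were 0.31, 0.40, 0.48 and 0.40, and under cyclic loess 0.42, 0.50, 0.55 and 0.43. Cyclic loess also gave the Golgi, cholesterol and luminal lists medians of 0.49, 0.46 and 0.63, and the mean of all probe sets gave the Golgi and translocation lists 0.43 and 0.33.

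**Figure D3:**
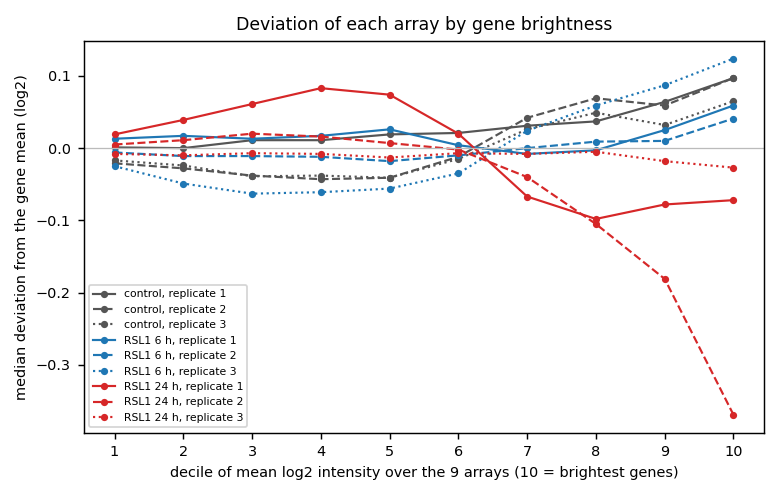
Median log2 deviation from the gene mean (vertical axis) in 10 equal sets of genes ordered by mean log2 intensity (horizontal axis), 1 line per array, coloured by group. In the brightest set the 24 h replicate 2 array lies at -0.37, the lowest of the 9 arrays.

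The third comparison set 24 h against 6 h, which equals the difference of the 2 contrasts with control, since both used the same controls. No vehicle group had a given harvest time, so hours in culture cannot be told apart from a change in the RSL1 effect. LOX did not pass at 6 h (log2 4.39 ± 0.31 against 4.38 ± 0.43 in the controls, mean ± SD, n = 3 arrays each), at a level below the array medians where a small change may not show. It read 11.6-fold higher at 24 h than at 6 h, a size that depends on that low level, as for LINC02475. TMEM45A was 8.62-fold higher, CUZD1 6.29-fold, LINC02475 6.25-fold and ADA2 5.62-fold (adjusted p between 6.38e-07 and 7.11e-05). TTK, a kinase of the spindle checkpoint, was 5.59-fold lower at 24 h than at 6 h, ANLN 5.19-fold, ASPM 4.42-fold, MAP3K20 4.26-fold and RRM2 4.19-fold (adjusted p between 3.2e-06 and 8.6e-05). For each of these genes all 3 arrays at 24 h lay on the same side of all 3 arrays at 6 h, which was a condition of being named.

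Of the lists, cell cycle genes were lower at 24 h than at 6 h (30 of 32 fell; median -1.34, camera adjusted p = 4.07e-38; adjusted p = 0.0682 with an estimated correlation). ER chaperones were higher (20 of 29 rose; median 0.52, camera adjusted p = 7.01e-14; adjusted p = 0.312 with an estimated correlation), as were cholesterol genes (10 of 18 rose; median 0.32, adjusted p = 3.15e-08; adjusted p = 0.0682 with an estimated correlation). Transport genes followed (16 of 37 rose, 1 fell; median 0.28, adjusted p = 4.81e-08; adjusted p = 0.425 with an estimated correlation), then androgen response genes (11 of 20 rose, 2 fell; median 0.45, adjusted p = 7.71e-07; adjusted p = 0.191 with an estimated correlation). Hypoxia genes were higher too (9 of 18 rose; median 0.26, adjusted p = 0.000259; adjusted p = 0.425 with an estimated correlation). Heat shock genes were lower (10 of 14 fell, 1 rose; median -0.48, adjusted p = 0.000327; adjusted p = 0.425 with an estimated correlation), and so were p53 genes (9 of 19 fell, 2 rose; median -0.17, adjusted p = 0.00495; adjusted p = 0.425 with an estimated correlation). Adjusted over the list alone, the counts of these 8 lists were 32 lower, 24 higher, 13 higher, 17 higher and 2 lower, 11 higher and 2 lower, 9 higher, 10 lower and 1 higher, and 9 lower and 2 higher.

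Luminal markers (4 of 10 rose, 1 fell; median 0.27, adjusted p = 0.0162), immediate early genes (5 of 19 rose, 1 fell; median 0.20, adjusted p = 0.0341) and genes of N-glycosylation in the ER (5 of 24 rose, 2 fell; median 0.16, adjusted p = 0.0481) were also called higher at 24 h than at 6 h. With an estimated correlation these had adjusted p = 0.425, 0.376 and 0.652, and adjusted over the list alone 5 higher and 2 lower, 7 and 1, and 7 and 3. The first of these calls ended without 24 h replicate 3 (adjusted p = 0.101), as did the second (0.11), whose median was 0.13 without 6 h replicate 3 and 0.12 without 24 h replicate 1, and which had 3 rises without 6 h replicate 1 or 3. The N-glycosylation list had 11 rises without 24 h replicate 2. The N-glycosylation call ended with the replicate block (0.0676), in fry (0.284), and without control 1 (0.0539), control 2 (0.0528), 6 h replicate 1 (0.133), 6 h replicate 2 (0.0859), 24 h replicate 1 (0.0677) or 24 h replicate 3 (0.323). The other 11 lists were not called by camera, with adjusted p between 0.0556 and 0.936, while fry called the CREB3 family, interferon and basal lists (adjusted p = 0.0159, 0.00823 and 0.018). Of these, the ATF4 list passed without 6 h replicate 3 (0.0212) or 24 h replicate 2 (0.0123), the list of ER translocation and signal peptide processing without the same arrays (0.0297 and 0.000112), and the list of basal epithelial markers without 6 h replicate 1 (0.0378). The ATF4, translocation and Golgi lists passed after quantile normalization again and after cyclic loess.

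In all, 1171 genes were higher and 2474 lower at 24 h than at 6 h, 5706 genes passed at an unadjusted p under 0.05, and 1781 were higher with the replicate number as a block. Without 6 h replicate 3, 1536 were lower. Higher genes made up 32.1% of the calls, 43.3% after quantile normalization again (1655 higher, 2170 lower) and 47.2% after cyclic loess (1710 higher, 1911 lower). Medians under these scalings, in that order, were 0.44 and 0.52 for the transport list, 0.32 and 0.38 for N-glycosylation, -0.30 and -0.23 for heat shock, 0.42 and 0.46 for hypoxia, and 0.50 and 0.56 for luminal markers. Without 24 h replicate 2 the transport median was 0.43 and the N-glycosylation median 0.26. The p53 call ended without dim genes (adjusted p = 0.0982, median -0.29) and after cyclic loess (0.0611), and the mean of all probe sets gave it a median of -0.34.

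Of the 385 genes that rose at 6 h, 126 were higher again at 24 h than at 6 h and 90 were lower at 24 h than at 6 h. The other 169 were not called between the times, which does not show that they stayed the same. These genes were picked on the same 6 h arrays that enter this comparison. SIAH2 was among those that came down, from 10.36 ± 0.19 at 6 h to 8.61 ± 0.17 at 24 h (log2, mean ± SD, n = 3 arrays each), as was HES1. Of the 162 genes that fell at 6 h, 22 were lower again at 24 h, among them ID1, 34 were higher and 106 were not called between the times. The shared calls at 6 h and 24 h, in the same direction, numbered 417, of which 297 were higher and 120 lower. Independent lists of these sizes would share 56.6 (30.8 higher and 25.7 lower), and unchanged groups simulated against the shared controls shared 0 on average over 100 draws. Unchanged groups are expected to give few calls at either time, so this 0 does not show how much shared controls add. These simulated arrays were independent, so the correlations of same-number arrays are left out of every simulated value here. The log2 changes at both times correlated across genes with r = 0.536, and such simulated groups gave 0.5, so r itself is no evidence of a shared effect, and genes are not independent replicates. The same sign was seen in 66% of genes, against 66.7% simulated. The covariance was 0.0402 against 0.00662 simulated, a difference of 0.0335. With the 3 controls divided 1 against 2, a test added after values were seen in which no control served both times, the covariance was 0.0326 to 0.0383 in 5 of the 6 divisions, and 0.0256 with control 1 alone for 6 h. The shared calls were not counted with divided controls, so part of their excess may come from the shared controls, and part of either excess from same-number arrays. The shared count was 248 without control 3, 242 without 6 h replicate 2 and 266 without 6 h replicate 3. Over the 3 groups together, 4571 genes passed the F test.

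Another 18 genes were called at both times in opposite directions, 9 rising first and 9 falling first. Only 5 of them kept both calls without any 1 array, and these were named after their values were seen. NIN, a centrosome protein, rose 1.91-fold at 6 h and was 1.72-fold lower than control at 24 h, and MTUS1 rose 1.79-fold and was then 1.38-fold lower. C5orf34 rose 1.63-fold and was then 1.54-fold lower. PDE9A, a cyclic GMP phosphodiesterase, was 1.54-fold lower at 6 h and 1.29-fold higher at 24 h, and TSC22D3, a glucocorticoid-induced gene, 1.47-fold lower and then 1.42-fold higher. In these 5 genes the adjusted p lay between 0.000373 and 0.00758 at 6 h and between 0.00078 and 0.00584 at 24 h. With the mean of all probe sets, TSC22D3 did not pass at 6 h and PDE9A did not pass at 24 h.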

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

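Many genes and lists changed by a different amount at 24 h than at 6 h, and the difference itself was tested in limma as the contrast between the 24 h and 6 h arrays. Both brightness tests of the ribosomal families were chosen only after their result was seen, as were the gene families and genes of opposite direction. Values in parentheses beside a gene or list in this and the next 3 paragraphs are the log2 effect at 24 h minus the log2 effect at 6 h. Each of these differences had an adjusted p under 0.05. Values marked as adjusted p are not effects.

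Genes of cell division, DNA synthesis and mitosis were lower at 24 h than at 6 h: ANLN (-2.38), KIF23 (-2.03), ASPM (-2.14), RRM2 (-2.07), NDC80 (-2.01), KIF20A (-1.72), TOP2A (-1.93), TTK (-2.48), CCNA2 (-1.72), CDC20 (-1.41), CENPF (-1.44) and CENPU (-1.85). Lower too were the kinases and damage or stress genes MAP3K20 (-2.09), DAPK1 (-1.85), SESN1 (-0.41), DDB2 (-0.90), GCLM (-0.42), GCLC (-0.61) and TP53INP1 (-0.90), the nuclear pore, chaperonin and ribosomal genes NUP85 (-1.10), NUP205 (-1.01), CCT6A (-0.78), CCT3 (-0.75) and MRPL15 (-0.79), and TUBB3 (-0.43), DDC (-0.49) and ACTA2 (-0.79). The early responders HES1 (-1.02) and SIAH2 (-1.75) came down from their level at 6 h, and ID1 (-1.15), NIN (-1.71), MTUS1 (-1.31) and C5orf34 (-1.33) were lower as well.

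Higher at 24 h than at 6 h were the secretory genes KDELR3 (1.85), MIA3 (0.88), EDEM2 (0.84), CRELD2 (0.91), TRAM1 (0.64), SRPRA (0.54), ALG1 (0.37), GALNT7 (0.65) and MAN1A1 (1.38). The matrix, membrane and secreted products LOX (3.53), TMEM45A (3.11), CUZD1 (2.65), ADA2 (2.49), AQP3 (2.05), P4HA1 (1.23), ANXA2 (2.11) and ANXA5 (1.42) were higher, with LINC02475 (2.64), DXO (2.03), MTUS2 (1.43), IKBIP (1.02) and MRPS18A (0.91). Lipid, androgen and hypoxia genes in this direction were STARD4 (0.95), INSIG1 (1.03), FASN (0.53), STEAP4 (2.42), NDRG1 (1.78), PMEPA1 (0.86), ANKRD37 (0.85), HK2 (0.29) and VEGFA (0.81). Regulators and stress genes were CREB3 (0.82), ATF3 (1.26), JUN (0.32), KLF6 (1.29), KLF10 (0.68), PTCH1 (0.54), DUSP1 (0.55), RGS2 (1.36), CRYAB (1.31), PDE9A (0.99), TSC22D3 (1.06) and AKR1B10 (0.29). Interferon response and marker genes were IRF7 (0.47), ISG20 (1.14), IFI6 (0.55), TRIM29 (1.252), CD24 (1.24), KRT8 (0.90) and TAGLN (0.92). Among these, ATF3, PMEPA1, PDE9A and TSC22D3 were below control at 6 h and above it at 24 h, and NIN, MTUS1 and C5orf34 the reverse. ATF3 and PMEPA1 are not among the 5 genes that kept both calls without any 1 array. With the mean of all probe sets, TSC22D3 did not pass at 6 h and PDE9A did not pass at 24 h.

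Of the lists, the median difference was that of ER chaperones and ER-associated degradation (0.52), ER-Golgi transport coats and cargo receptors (0.28), N-glycosylation in the ER (0.16), androgen response (0.45), cell cycle (-1.34), p53 targets and apoptosis (-0.17), cholesterol and fatty acid synthesis (0.32), immediate early genes (0.20), cytosolic heat shock (-0.48), hypoxia and glycolysis (0.26) and luminal epithelial markers (0.27). With an estimated correlation none of these 11 lists passed (adjusted p from 0.0682 to 0.652). The N-glycosylation list also did not pass with the replicate block (adjusted p = 0.0676) or in fry (adjusted p = 0.284). Without 24 h replicate 3 the calls of the luminal, immediate early and N-glycosylation lists were lost, with adjusted p of 0.101, 0.11 and 0.323. The N-glycosylation call was also lost without control 1 or 2, 6 h replicate 1 or 2, or 24 h replicate 1 (adjusted p = 0.0539, 0.0528, 0.133, 0.0859 and 0.0677).

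Probe sets without a single gene name were not part of the comparisons above. Of 13522 tested, 115 were called at 6 h (83 higher, 32 lower) and 919 at 24 h (410 higher, 509 lower). The largest change at 24 h was that of a probe set that rose by 2.02 at 6 h and 3.95 at 24 h on the log2 scale.

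Other splits of the arrays were compared with the real one. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. At 6 h 547 genes were called, at 24 h 4727 and between the times 3645, in each case only by 1 split, the real one. The highest other split called 0 in limma in each comparison, with at most 1435, 2322 and 2675 genes at an unadjusted p under 0.05 against 2000, 6520 and 5706. Of the other splits, 3 part all same-number pairs as the real one does, and these gave at most 201, 370 and 262. For the F test over the groups, 1 of 100 splits drawn from 280 gave as many genes as the real 4571. The highest other gave 3497, which makes chance an unlikely source of that count. The splits not drawn could differ, and the draws ignored the correlations of same-number arrays, so chance is not excluded. The 4 highest others (3497, 3463, 3024 and 3002) keep the 24 h arrays together, which points to that group as the main structure of the arrays, and the next gave 301.

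Cytosolic ribosomal protein genes, 54 in number and among the brightest measured, had a median of -0.29 at 24 h, -0.11 without 24 h replicate 2 and -0.42 without 24 h replicate 3, with 3 fallen, 1 and 36 (medians of -0.20, -0.63 and -0.02 in the 24 h arrays). Falls numbered 6 without 24 h replicate 1, 1 without 6 h replicate 2 or 3 and 8 after median centring, and none passed in limma without any one control or under the other scalings, where the median was -0.005 after quantile normalization again and 0.08 after cyclic loess, so the direction flips. Array brightness left by the authors' normalization and a fall of these genes cannot be told apart, since 49 of the 54 lie in the brightest of 40 sets of genes, whose values quantile normalization makes alike in all arrays. For the 75 mitochondrial ribosomal protein genes the same test gave -0.31 against -0.42 (49 fell, 1 rose), and -0.22 after cyclic loess (27 fell, 2 rose), which argues against brightness as the whole cause. No biological explanation of these families was tested.

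The cell cycle list fell at 24 h, with a median of -1.38. Array brightness left by the authors' normalization is argued against by a median of -1.27 after quantile normalization again. A general fall of genes of that brightness is argued against as well, since the list median lay at percentile 0 of 10000 random lists matched on mean expression, of which the lowest had -0.48. What stays open is whether hours in culture differ between controls and 24 h cultures, since 0 vehicle groups have a harvest time in the labels. RSL1 acting without the transgene, and AIbZIP itself, also stay open and could not be tested in this design.

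In control replicate 1, genes at least 2-fold higher at 24 h (293) lay low, with a median deviation of -0.12 from the control mean. Array brightness is argued against, since that value lay at percentile 0 of 10000 lists matched on mean expression. The same genes lay at percentile 100 in control replicates 2 and 3 (0.10 and 0.01). Deviations were taken from the mean of these controls, so this largely restates the low value in control replicate 1. An extreme percentile was still not particular to this array, since these genes lay at percentile 0 in 24 h replicate 2 (-0.111). They lay at percentile 100 in 24 h replicate 3 (0.105). Some induction in control replicates 2 and 3 would put the genes at least 2-fold lower at 24 h (333) high in control replicate 1. They were low there instead (-0.09, percentile 0). Those genes were also low in the other arrays numbered 1, so the test cannot decide whether induction is part of this pattern. A shared difference of the arrays numbered 1 may be part of it and cannot be told apart: the risers lay at percentile 2.51 in the 6 h array numbered 1 and at 81.1 in the 24 h array numbered 1, while the genes lower at 24 h lay at percentile 0 in both (-0.08 and -0.17), as such a difference would give. No biological explanation was tested.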

How the results depend on the processing

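The fits with cyclic loess, with quantile normalization and no 24 h replicate 2, and with quantile normalization and the replicate block were chosen only after the results were seen. The causes of the differences below were not tested.

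With all probe sets tested, 766 stood in place of the genes risen at 6 h, 258 of the genes fallen at 6 h, 3331 of the genes risen at 24 h, 5629 of the genes fallen at 24 h, 2234 of the genes higher at 24 h than at 6 h, 4139 of the genes lower at 24 h than at 6 h, 8443 of the genes changed over the 3 groups and 797 of the shared calls at 6 h and 24 h. These are counts of probe sets, of which a gene can have several. With a change of at least 1.5 times the same counts were 256, 63, 755, 1369, 461, 1058, 2202 and 225. At an adjusted p under 0.01 there were 225 rises and 63 falls at 6 h, 703 higher and 1500 lower genes between the times, 2982 by F test and 223 shared.

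With the replicate block 605 rose and 412 fell at 6 h, 1781 were higher at 24 h than at 6 h and the shared calls at 6 h and 24 h numbered 770. The block also brought CREB3L4 at 24 h past the threshold (log2 change -0.26 in both fits, adjusted p = 0.0236 in limma; lower in all 3 arrays than the control mean), where the other settings gave -0.11 to -0.33 and adjusted p from 0.096 to 0.633. At 24 h the block gave the p53 and basal lists adjusted p of 0.0435 and 0.0462. Apart from these, SRPRB at 6 h and the N-glycosylation list between the times, it changed no call of a named gene or list.

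Camera with an estimated correlation called 0 lists in each contrast (0, 0 and 0; 3, 3 and 4 at an unadjusted p under 0.05), and fry called 4 at 6 h and 16 at 24 h. Quantile normalization again without 24 h replicate 2 gave 251 falls at 6 h. Quantile normalization with the block gave 654 rises and 481 falls at 6 h, 2605 rises at 24 h, 2309 higher genes between the times and 858 shared calls at 6 h and 24 h.

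Leaving out 1 array at a time gave 238 to 418 rises and 63 to 199 falls at 6 h, 1213 to 1613 rises and 2329 to 3457 falls at 24 h, 841 to 1228 higher and 1536 to 2971 lower genes between the times, 3689 to 4803 by F test and 242 to 451 shared. CREB3L4 ranged from -0.20 to 0.00 at 6 h and from -0.33 to -0.15 at 24 h.

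Of the single genes and lists, 2446 comparisons with other settings gave the same call, 52 lost it and 44 gained it. With 1 array left out these numbers were 2203, 89 and 12. None was reversed in these settings. Another probe set for CREB3L4 gave no value, since the gene has no other probe set.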

Other observations

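Gene families outside the 22 lists were examined at 24 h, and all of these tests were chosen only after the results were seen. Of 26 nucleoporins 20 fell and 1 rose (median -0.52; -0.43 after quantile normalization again and -0.36 after cyclic loess), with NUP85 2.34-fold and NUP205 2.09-fold lower. Of 18 centromere proteins 14 fell (median -0.87; -0.83 and -0.82), with CENPF 3.08-fold and CENPU 3.46-fold lower. Of 8 cytosolic chaperonin subunits, which fold actin and tubulin, 6 fell (median -0.67; -0.48 and -0.37), with CCT6A 1.78-fold and CCT3 1.69-fold lower. Of 34 proteasome subunits 18 fell and 1 rose (median -0.32; -0.18 and -0.08; -0.21 without 24 h replicate 2). The falls numbered 13 and 6 under these scalings, 11 without any one control and 12 without 24 h replicate 2. Among mitochondrial ribosomal proteins MRPL15 was 1.76-fold lower, while MRPS18A rose 1.96-fold.

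Families that rose in part were fewer in calls. Over all 19775 genes 1584 rose and 3143 fell at 24 h, and the family shares were not tested against these. The share of keratins that rose was not far above that of all genes. Of 11 annexins, which bind membranes in the presence of calcium, 4 rose (median 0.23; 0.12 without control 1), with ANXA2 4.87-fold and ANXA5 3.94-fold higher. Of 20 claudins 4 rose (median 0.13), of 44 keratins 5 rose (median 0.12; 0.08 without control 2), and of 17 GALNT transferases, which start O-linked glycans, 5 rose (median 0.10; 0.22 without control 1, 0.06 without control 3 or 24 h replicate 1, and 0.19 without 24 h replicate 2). Only 3 of the GALNT transferases rose without control 3 or 24 h replicate 2. In these 4 families the medians kept their sign in the scalings run.

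At 6 h 12 of 37 transport genes and 1 of 29 ER chaperones rose, and at 24 h 27 and 22. Fisher's exact test of these shares (p = 0.00403 and p = 1) was chosen after the counts were seen and restates them, so it is no separate evidence for the candidate explanation, a hypothesis, that transport coat genes rise earlier than ER chaperones. Leaving out 1 of the 6 arrays compared lowered the transport calls to 4, 8 and 5 without controls 1, 2 and 3 and to 6, 4 and 4 without 6 h replicates 1, 2 and 3, against 1 chaperone each time (exact p = 0.375, 0.0663, 0.218, 0.124, 0.375 and 0.375). The sizes of the shifts changed little, since with any 1 array left out the 6 h median of the list of ER-Golgi transport coats and cargo receptors stayed between 0.257 and 0.315 and that of ER chaperones and ER-associated degradation between -0.021 and 0.015. With the mean of all probe sets, however, camera called the list of ER chaperones at 6 h, as given above. Between the times the lists of ER chaperones and ER-associated degradation and of ER-Golgi transport coats and cargo receptors were higher by medians of 0.52 and 0.28, by 0.63 and 0.44 after quantile normalization again, by 0.70 and 0.52 after cyclic loess and by 0.60 and 0.43 without 24 h replicate 2, and whether these medians differ was not tested.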
